A study of Mus musculus with 14 samples.

How the data were processed

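The series measured back skin of young (2-month-old) and aged (24-month-old) female mice. Skin cells were released with trypsin and sorted by flow cytometry, per the labels' protocols. Hair follicle stem cells (HFSC) were lineage-negative, integrin α6-high, CD34-positive and Sca1-negative cells, and epidermal stem cells (EpdSC) were lineage-negative, integrin α6-high, CD34-negative and Sca1-positive cells. The 14 samples fell into 10 groups. These were 8 RNA-seq libraries, 2 for each population and age, 4 ATAC-seq libraries, 1 for each population and age, and 2 10x single-cell libraries, 1 for each age, from lineage-negative, integrin α6-positive cells. Every sample had a group in the labels. The labels give the mouse strain under 2 different names in different fields, so no strain is stated here.

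The authors deposited RNA-seq read counts per gene, in whole numbers that are not normalised, 1 count column per library, with gene identifiers and symbols. The submitters' processing notes name STAR, Bowtie and Cell Ranger without versions and the genome build mm10. The strand setting of the RNA counting and the annotation release are not given in the sources used here. Reads of a gene and of an antisense partner were therefore not separated, and a near-identical copy of a gene can hold part of its reads. For ATAC-seq the authors deposited counts per 500-base window along the genome, in overlapping steps. Only non-overlapping windows, 5267565 of 10923515, were used here. Whether duplicate reads were removed and whether reads were shifted for the enzyme's binding site is not given in the sources used here. For 10x the deposited matrices hold counts of unique molecular identifiers (UMIs) for 737280 barcodes in each library, without a cell filter.

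RNA counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by the trimmed mean of M values, genes were filtered with filterByExpr, which left 21464 genes, and the quasi-likelihood test was run on 1 fit of all 8 libraries, with a term per group and no covariate. The 4 groups shared 1 estimate of the spread (common biological coefficient of variation 0.277). The 5 contrasts were aged against young in HFSC, aged against young in EpdSC, EpdSC against HFSC in young mice, EpdSC against HFSC in aged mice, and the difference between the age effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene in the text comes from this test unless another is named. Standard errors (SE) of log2 fold changes were taken as the absolute fold change over the square root of the F statistic. Levels are counts-per-million values (CPM) as mean ± SD of 2 libraries. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

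The comparisons, the tests, 27 gene lists, 20 sets of cell type markers, the rule for named genes and most alternatives were fixed before the data were examined. Of these lists, 45 had 3 or more measured members and were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Several lists overlap, and many members of the marker sets are also expressed by the sorted keratinocytes. Named genes were the sort markers Cd34, Ly6a and Itga6, and up to 6 rises and 6 falls with the largest fold change. These were called genes with a symbol that is not a predicted gene, a pseudogene or an antisense name, a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Members of gene lists followed. Lists that camera called, or with 3 or more called members, gave up to 4 called members with the smallest p. Lists without a called member gave up to 2. Any other gene is named as chosen after its values were seen. Some items that these rules took are not reported here.

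Gene positions came from the RefSeq gene table of GRCm38.p6, the build of mm10, for 17757 genes. This table has no strand, so the promoter was taken as the gene end with more ATAC counts within 1000 bases, over the 4 libraries scaled alike. Windows around it were summed per gene and divided by the library's counts, and log2 ratios used a pseudocount of 0.5 and genes with at least 20 counts over the pair. Windows with at least 4 CPM in either library of the pair were compared at 4-fold. With 1 library per group no test was run and no p-value is given. Intervals are 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. The median of a gene list was placed among 10000 random lists of the same size matched on mean RNA expression.

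For 10x, a barcode was kept with at least the 99th percentile of UMIs among the 4000 deepest barcodes divided by 10, 500 or more genes and at most 10% mitochondrial UMIs. This kept 4038 young and 4469 aged barcodes, beside 4000 captured cells per library in the labels. Scrublet marked 4 young and 1 aged cell as doublets. At this share the caller has not worked, so doublets remain in the data. The remaining cells were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster was named from the fixed markers where at least 3 of them, and at least 30% of the set, lay 2-fold above the median of all clusters at 100 CPM or more. Clusters left over were then set against the median of the clusters named before, without the proliferating ones, which named all 5 interfollicular basal-like clusters. This naming rule was chosen after the clusters and the cells of each library in them were seen, and it was tried in other forms. Counts were summed per class and library, with log2 ratios of CPM. Their 95% intervals are those of a ratio of Poisson counts (exact conditional binomial), those of shares are exact Clopper-Pearson intervals, and all cover counting error only. Genes were named by size, the 6 highest and 6 lowest ratios per class among genes with 100 or more UMIs whose interval excluded 0. Depth was checked by thinning each cell to 1000 UMIs, which left out 118 aged and 0 young cells.

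The sum of counts was 25126808 to 35905505 per RNA-seq library and 8243611 to 37322834 per ATAC-seq library over the windows used. Replicates differed by more than sampling noise in every RNA group, with a chi-square per degree of freedom between 28.31 and 60.05, so no pair was a repeat of 1 library. The RNA test was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In the HFSC age comparison 44 and 84 of them were recovered, among 20143 genes. In the EpdSC age comparison the numbers were 48 and 84, among 20109 genes. For EpdSC against HFSC they were 43 and 85 in young mice and 51 and 84 in aged mice, and for the difference between the age effects 12 and 74. Between 5 and 14 unchanged genes were called, and no recovered gene had the wrong sign. Their share of the calls was above the 0.05 that the threshold aims at, except for EpdSC against HFSC in young mice. Changed genes were drawn from those with a mean of at least 1 CPM, so recovery of lower genes was not measured. On simulated Poisson counts, which the intervals assume, 94.9% of the ATAC intervals and 95.73% of the 10x intervals held the true ratio. This checks the calculation only, and real counts can vary more.

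Alternatives were DESeq2 1.42.0, other scaling factors, other filters on low counts, a replicate block, a fit of only the libraries compared, and leaving out each library in turn. For ATAC and 10x they were other promoter widths, minimum counts, folds, scalings, cell filters and cluster resolutions. The replicate numbers in the labels are not said to mark animals or days. A choice between strand columns was planned and not run, because there was 1 count column. Sequence context was not analysed here, since no genome sequence was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.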

Results

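Transcripts, open chromatin and single cells were profiled in sorted stem cell populations of mouse back skin at 2 and 24 months of age. HFSC, the CD34-positive stem cells of the hair follicle bulge, and EpdSC, the Sca1-positive basal cells of the epidermis, were each sequenced as 2 RNA-seq libraries and 1 ATAC-seq library per age. ATAC-seq counts transposase insertions and so measures chromatin accessibility. RNA-seq libraries held 28790403 and 25126808 counts in young HFSC, 28292017 and 30512283 in aged HFSC, 35905505 and 29923009 in young EpdSC, and 34181623 and 31271835 in aged EpdSC. The mitochondrial ribosomal RNA mt-Rnr2 took 14.96% and 15.23% of counts in young HFSC, 16.76% and 16.74% in aged HFSC, and 13.02% to 14.02% in EpdSC. ATAC-seq libraries held 26169738 counts in young HFSC, 8243611 in aged HFSC, 37322834 in young EpdSC and 22933001 in aged EpdSC. The 10x libraries gave 4034 young cells with a median of 3918 UMIs and 4468 aged cells with a median of 2271 UMIs.

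The comparison of aged with young HFSC asked which transcripts differ with age in follicle stem cells. Ly6e (ENSMUSG00000022587.14, chromosome 15, 74955025 to 74959904), a member of the Ly6 family of membrane-anchored proteins, rose from 9.08 ± 0.384 to 77.2 ± 20.7 CPM (SD, n = 2 libraries per group), a log2 fold change of 3.09 (SE 0.207, edgeR adjusted p = 0.000187). Sp100 (ENSMUSG00000026222.16, chromosome 1, 85649948 to 85709998), a component of nuclear bodies, rose from 0.940 ± 0.272 to 10.8 ± 0.589 CPM, by 3.51 (SE 0.409, edgeR adjusted p = 0.0089). The imprinted gene Peg3 (ENSMUSG00000002265.16, chromosome 7, 6703892 to 6730462) had the clearest fall, from 111 ± 3.16 to 20.2 ± 4.71 CPM, with a log2 fold change of -2.46 (SE 0.227, edgeR adjusted p = 0.00278). Ltbp1 (ENSMUSG00000001870.15, chromosome 17, 75005480 to 75392512), which binds latent TGF-beta in the matrix, fell from 195 ± 0.205 to 77.4 ± 0.647 CPM, with a log2 fold change of -1.33 (SE 0.189, edgeR adjusted p = 0.0181). Hhip, a membrane protein that binds hedgehog ligands, was at 11.8 ± 2.52 CPM in young and 0.919 ± 0.787 CPM in aged HFSC (log2 fold change -3.68, SE 0.594, edgeR adjusted p = 0.0317).

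In this comparison 63 genes rose and 16 fell, and 61 and 14 of them changed at least 2-fold. In a fit of only the 4 libraries compared 7 rose and 2 fell, and with a filter of 1 CPM in 2 libraries 43 and 9. Without a filter on low counts the numbers were 470 and 192, with DESeq2 273 and 94, and with the replicate number as a block 123 and 37. The other rises of largest size were Zmat4 (log2 fold change 3.41, SE 0.431), Aff2 (3.07, SE 0.385), Sdr16c6 (2.75, SE 0.446) and Acta2 (4.20, SE 0.762). Acta2, the smooth muscle actin, had 1.81 and 11.7 CPM in the aged libraries, and without aged HFSC replicate 2 it was no longer called. Other large falls were Fam46c (log2 fold change -1.64, SE 0.266), Enc1 (-1.50, SE 0.254) and Dlc1, a GTPase-activating protein (-1.43, SE 0.158). The sort markers were not called. Cd34 had a log2 fold change of -0.63 (SE 0.265, edgeR adjusted p = 0.586), Ly6a, which encodes Sca1, 1.77 (SE 0.405, edgeR adjusted p = 0.123) and Itga6 0.14 (SE 0.165, edgeR adjusted p = 0.981). Without aged HFSC replicate 2 there were 10 rises and 2 falls, without aged HFSC replicate 1 137 and 24, and without young HFSC replicate 2 101 and 23. Without young HFSC replicate 1 there were 54 rises and 44 falls, and 34 of these calls were among the 79, so the excess of rises depended on that library. EpdSC libraries enter only the scaling, the filter on low counts and the shared spread. Rises and falls were 122 and 36 without young EpdSC replicate 1, 116 and 31 without its replicate 2, 79 and 30 without aged EpdSC replicate 1 and 77 and 25 without its replicate 2.

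**Figure D1:**
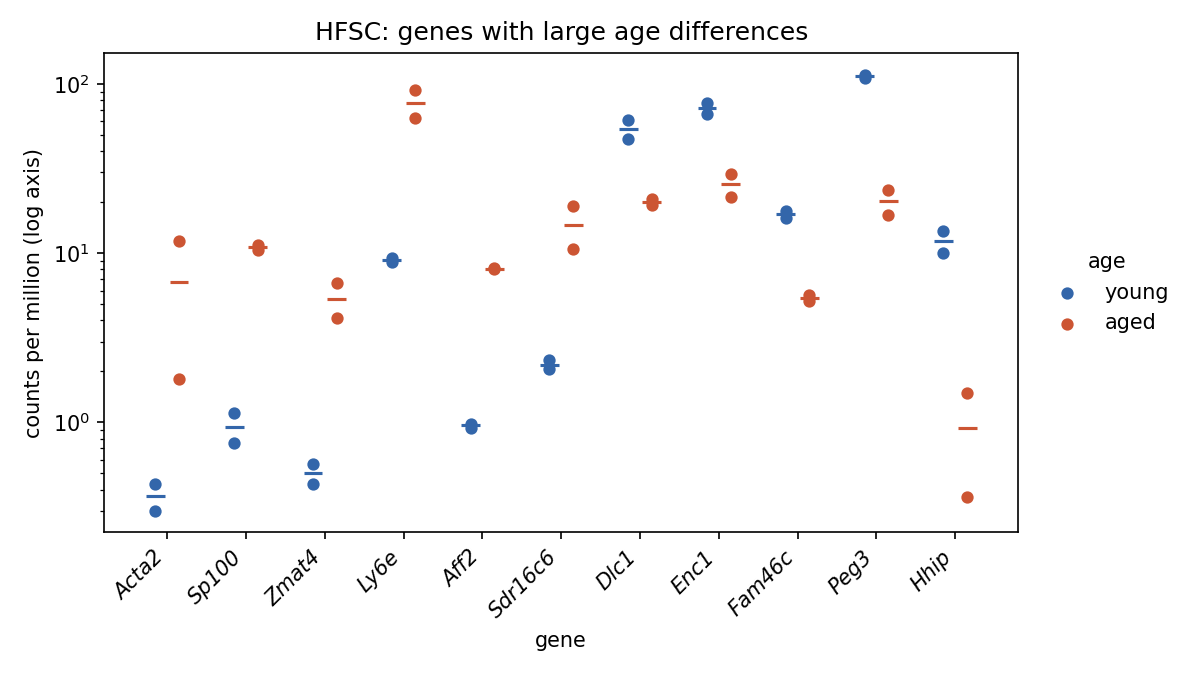
CPM (log axis) of 11 HFSC genes with large age differences; each point is 1 of 2 libraries per age and each line a mean. Ly6e lies at 9.35 and 8.81 CPM in young and 62.5 and 91.9 CPM in aged HFSC.

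Of the 24 genes called here that the naming rule took, Ly6e, Sp100, Peg3, Dlc1 and Ly6d, 5 in all, remained called whichever library was left out, and all 24 kept their sign. Without aged HFSC replicate 2, 19 of the 24 were no longer called. Among them were Acta2, Aff2, B2m, Csf1, Enc1, Fam46c, Far2, Gbp2, Hhip, Irf1, Junb, Ltbp1, Nlrc5, Plau, Psmb8, Sdr16c6 and Zmat4. Losses were 3 without aged HFSC replicate 1, 11 without young HFSC replicate 1 and 10 without young HFSC replicate 2.

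Genes of the epidermis and of sebaceous and lipid-producing cells were higher in aged HFSC. All 12 sebaceous markers were higher, with 1 called over all genes (Far2, a fatty acyl-CoA reductase, log2 fold change 2.02, SE 0.311) and 10 adjusted over the list alone (camera adjusted p = 6.14e-10, adjusted p = 0.311 with an estimated correlation). Of 25 genes of cholesterol and fatty acid synthesis 23 were higher, 1 called over all genes and 14 adjusted over the list alone (camera adjusted p = 1.38e-08, adjusted p = 0.472 with an estimated correlation). Of 29 genes of epidermal differentiation and the cornified envelope 22 were higher, with 0 called by edgeR over all genes (5 by DESeq2, 15 at an unadjusted p under 0.05) and 15 adjusted over the list alone (camera adjusted p = 4.05e-08, adjusted p = 0.398 with an estimated correlation). Krt1, a suprabasal keratin, had a log2 fold change of 2.74 (edgeR adjusted p = 0.0806). Of 11 suprabasal markers 9 were higher, 0 called by edgeR over all genes (3 by DESeq2, 8 unadjusted) and 8 adjusted over the list alone (camera adjusted p = 7.41e-05, adjusted p = 0.472 with an estimated correlation). Of 22 genes of the epidermal stem cell signature 17 were higher, with Ly6d, a keratinocyte surface protein, called over all genes (2.12, SE 0.276) and 10 up and 1 down adjusted over the list alone (camera adjusted p = 0.000164, adjusted p = 0.398 with an estimated correlation). Among interfollicular basal markers 10 of 11 were higher, 0 called by edgeR over all genes (4 by DESeq2, 7 unadjusted) and 6 adjusted over the list alone (camera adjusted p = 0.000457, adjusted p = 0.385 with an estimated correlation). Of 12 upper hair follicle markers 10 were higher, 0 called by edgeR over all genes (1 by DESeq2, 5 unadjusted) and 3 adjusted over the list alone (camera adjusted p = 0.00261, adjusted p = 0.472 with an estimated correlation). Across all 63 rises, 36 were also higher in EpdSC than in HFSC at both ages. Independent lists would share 6.39. In 20 simulations with aged HFSC unchanged, which show chance with no effect, 0.55 rises were called on average, 0.1 of them higher in EpdSC, so they do not measure what the shared libraries add among real rises. Part of the excess may come from the shared libraries and the shared estimate of the spread. Genes called higher in young EpdSC made up 45 of the 63 rises and 2 of the 16 falls, beside 2788 of all 21464 genes. That comparison also shares the young HFSC libraries, which may add to the 45. With such genes left out of the adjustment, 4 rises and 1 fall were called.

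Immune genes were also higher. All 18 genes of MHC and antigen presentation were higher, 3 called over all genes and 10 adjusted over the list alone (camera adjusted p = 5.53e-09, adjusted p = 0.472 with an estimated correlation). They were B2m, the light chain of class I molecules, from 294 ± 18.0 to 845 ± 411 CPM (log2 fold change 1.52, SE 0.257, edgeR adjusted p = 0.0363), Nlrc5, the class I transactivator (1.19, SE 0.201), and Psmb8, an immunoproteasome subunit (1.69, SE 0.301). Of 29 interferon response genes 20 were higher, with Gbp2 (1.89, SE 0.246) and Irf1 (1.09, SE 0.183) called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000383, adjusted p = 0.311 with an estimated correlation). Of 25 cytokine, chemokine and NF-kB genes 19 were higher, with Csf1, a macrophage growth factor, called (1.27, SE 0.22) and 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.472 with an estimated correlation). Of 23 immediate early genes 18 were higher, with Junb called (1.11, SE 0.179) and 10 up and 1 down adjusted over the list alone (camera adjusted p = 0.000164, adjusted p = 0.472 with an estimated correlation). Of 22 wound keratinocyte genes 17 were higher, with Plau, the urokinase protease, called (1.73, SE 0.222) and 4 adjusted over the list alone (camera adjusted p = 0.00443, adjusted p = 0.472 with an estimated correlation). Langerhans and myeloid markers were higher in 7 of 9 (camera adjusted p = 0.0504), and pericyte and smooth muscle markers in 7 of 8 (camera adjusted p = 0.0912).

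Ribosomal protein genes were higher in 41 of 42 with a median log2 fold change of 0.12 (camera adjusted p = 0.014, adjusted p = 0.782 with an estimated correlation), and genes of nuclear oxidative phosphorylation in 34 of 37 with a median of 0.16 (camera adjusted p = 0.0296, adjusted p = 0.799 with an estimated correlation). In both lists edgeR called 0 genes over all genes and 0 adjusted over the list alone, DESeq2 called 0, and 0 passed at an unadjusted p under 0.05. The basement membrane and extracellular matrix list was the 1 called downwards. Of its 40 genes 14 were higher, with Ltbp1 called over all genes and 2 up and 2 down adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.472 with an estimated correlation). The HFSC signature was higher in 5 of 24 genes (camera adjusted p = 0.0614), bulge markers in 3 of 12 (camera adjusted p = 0.204) and proliferating cell markers in 2 of 10 (camera adjusted p = 0.0504). Camera called 15 of 45 lists, 9 of them without aged HFSC replicate 2, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Fry called 3 at an adjusted p under 0.05, the interferon response (0.0296), interfollicular basal markers (0.0426) and sebaceous markers (0.0426). In 5 lists that camera did not call, the median, the mean and the test differed in sign.

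The comparison of aged with young EpdSC asked the same of the epidermis. Arc (ENSMUSG00000022602.14, chromosome 15, 74669081 to 74672570), an immediate early gene known from neurons, rose from 4.35 ± 1.83 to 53.4 ± 4.33 CPM, a log2 fold change of 3.61 (SE 0.367, edgeR adjusted p = 0.0054). Casp12 (ENSMUSG00000025887.10, chromosome 9, 5345442 to 5373034), an inflammatory caspase, rose from 2.64 ± 0.78 to 16.5 ± 0.894 CPM, by 2.64 (SE 0.302, edgeR adjusted p = 0.00702). Cadps2, a protein of vesicle release, rose by 3.16 (SE 0.357, edgeR adjusted p = 0.00702), Zmat4 by 3.28 (SE 0.412, edgeR adjusted p = 0.0138), and Igfbp5, an IGF-binding protein, by 3.25 (SE 0.46, edgeR adjusted p = 0.03). Ltbp1 fell from 13.0 ± 1.57 to 3.02 ± 1.08 CPM (log2 fold change -2.11, SE 0.216, edgeR adjusted p = 0.0054). Sema3e (ENSMUSG00000063531.7, chromosome 5, 14025276 to 14256689), a secreted guidance cue, fell from 11.5 ± 4.08 to 2.01 ± 1.27 CPM (-2.51, SE 0.366, edgeR adjusted p = 0.0366). The amino acid transporter gene Slc38a4 (-2.64, SE 0.402) and Rps4l (-2.57, SE 0.339) also fell, and Rps4l may share reads with its paralog Rps4x.

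In EpdSC 12 genes rose and 6 fell, all 18 at least 2-fold. At an unadjusted p under 0.05 there were 957 of 21464 genes, no more than would be reached with no effect. With DESeq2 60 rose and 25 fell, without a filter on low counts 159 and 80, with a filter of 1 CPM in 2 libraries 7 and 3, without the composition factor 8 and 3, and in a fit of only the 4 libraries compared 3 and 0. The total was 6 without aged EpdSC replicate 2 and 31 without young HFSC replicate 2. Of the 10 genes called that the naming rule took, 4 remained called whichever library was left out, among them Arc, Cadps2 and Ltbp1. Igfbp5, Casp12, Rps4l, Sema3e, Slc38a4 and Zmat4 lost the call without aged EpdSC replicate 2, and all 10 kept their sign.

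**Figure D2:**
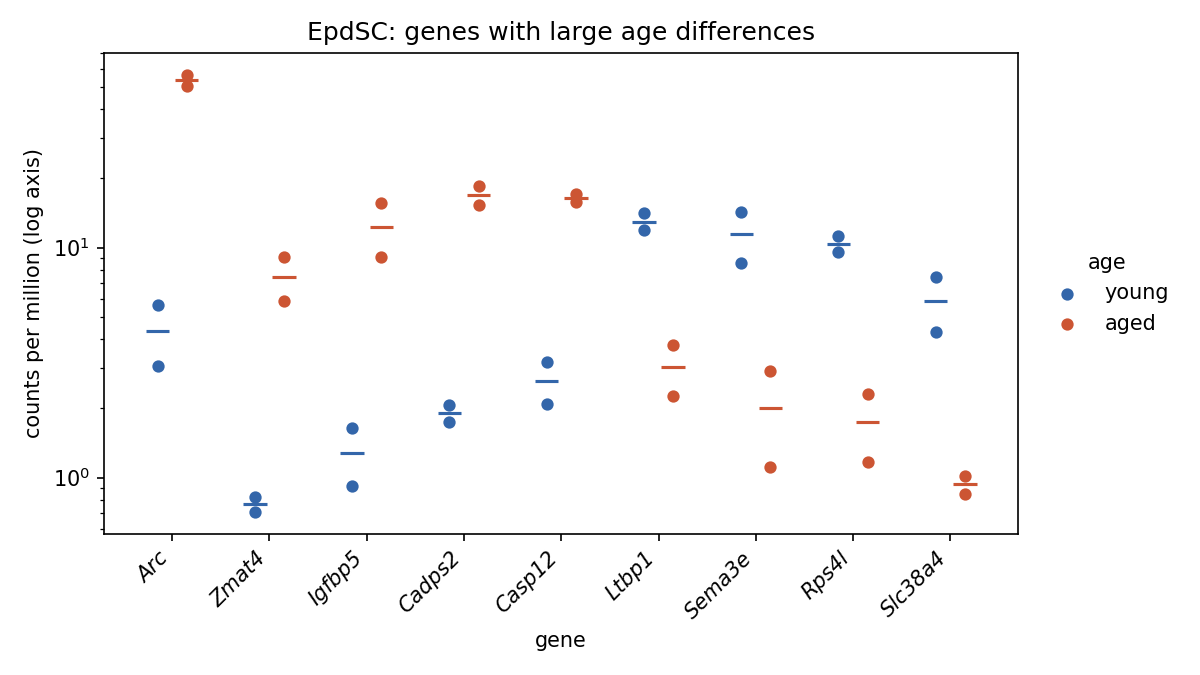
CPM (log axis) of 9 EpdSC genes with large age differences; each point is 1 of 2 libraries per age and each line a mean. The mean of Arc is 4.35 CPM in young and 53.4 CPM in aged EpdSC.

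Several groups were higher in aged EpdSC. In these lists edgeR called 0 genes over all genes, and DESeq2 called 1 each among the immediate early, cytokine and sebaceous lists and 0 in the others. Immediate early genes were higher in 19 of 23, 9 at an unadjusted p under 0.05 and 3 adjusted over the list alone (camera adjusted p = 0.000325, adjusted p = 0.855 with an estimated correlation). Cholesterol and fatty acid synthesis was higher in 21 of 25 (camera adjusted p = 0.00135), ribosomal proteins in 40 of 42 (camera adjusted p = 0.00148), epidermal differentiation in 24 of 29 (camera adjusted p = 0.00266) and suprabasal markers in 11 of 11 (camera adjusted p = 0.0129), each with 0 adjusted over the list alone and adjusted p = 0.855 with an estimated correlation. Sebaceous markers were higher in 11 of 12, 3 adjusted over the list alone (camera adjusted p = 0.00681), cytokine, chemokine and NF-kB genes in 20 of 25, 1 adjusted over the list alone (camera adjusted p = 0.0177), melanocyte markers in 6 of 8 (camera adjusted p = 0.0177) and inner bulge markers in 7 of 7 (camera adjusted p = 0.0465), both with 0 adjusted over the list alone, again with adjusted p = 0.855 with an estimated correlation. Langerhans and myeloid markers were lower, with 2 of 9 higher (camera adjusted p = 0.0194, adjusted p = 0.855 with an estimated correlation). Camera called 10 lists, 5 without aged EpdSC replicate 2 and 2 without young EpdSC replicate 2. Fry called 0 lists, and 2 of 45 had an unadjusted fry p under 0.05, near the number expected with no effect.

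Zmat4, Casp1 and Casp12 were among the 4 genes that rose in both populations, and Peg3 and Ltbp1 fell in both. These 6 shared calls stand beside 0.0352 rises and 0.00447 falls for independent lists, and 0 genes were called in opposite directions. Both comparisons came from 1 fit with the same estimate of the spread for each gene. A gene with a low estimate is called more easily in both, so independent lists share too few. Casp1 (5298517 to 5307281) and Casp12 (5345442 to 5373034) are also close to each other on chromosome 9 and may not be separate cases. Casp1, an inflammatory caspase, rose in HFSC from 11.2 ± 0.771 to 42.3 ± 12.7 CPM (log2 fold change 1.91, SE 0.231, edgeR adjusted p = 0.00926) and in EpdSC from 13.7 ± 2.89 to 46.1 ± 2.63 CPM (1.75, SE 0.228, edgeR adjusted p = 0.0176). Peg3 in EpdSC fell from 4.59 ± 0.449 to 0.656 ± 0.316 CPM (-2.81, SE 0.301, edgeR adjusted p = 0.00632). Casp1 in both populations and Peg3 in EpdSC were named because they were in this overlap, after their values were seen. Across all genes the age effects of both populations had a Pearson correlation of 0.0814; genes are not independent replicates. The overlap was 3 without aged HFSC replicate 2, 3 without aged EpdSC replicate 2 and 23 with DESeq2.

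Whether an age effect differed between the populations was tested directly. Ly6e was the 1 gene called, with a log2 age effect 2.70 higher in HFSC (SE 0.273, edgeR adjusted p = 0.0144). Its levels in EpdSC were 90.8 ± 13.5 CPM in young and 119 ± 4.53 CPM in aged mice. At an unadjusted p under 0.05 there were 980 of 21464 genes, no more than would be reached with no effect. DESeq2 called 87, and edgeR without a filter on low counts 285. The count was 0 without aged EpdSC replicate 2, 5 without aged EpdSC replicate 1, 6 and 5 without young EpdSC replicates 1 and 2, 17 and 63 without young HFSC replicates 1 and 2, and 35 without aged HFSC replicate 1. MHC and antigen presentation genes had a higher age effect in HFSC in 18 of 18, with 0 called by edgeR over all genes, 10 at an unadjusted p under 0.05 and 8 adjusted over the list alone (camera adjusted p = 4.15e-07, adjusted p = 0.8 with an estimated correlation). Nlrc5 differed by 1.30 (SE 0.279, edgeR adjusted p = 0.277) and H2-Ab1, a class II gene, by 2.24 (SE 0.559, edgeR adjusted p = 0.453). Sebaceous markers were higher in 10 of 12, 1 adjusted over the list alone (camera adjusted p = 0.00205, adjusted p = 0.706 with an estimated correlation), and Langerhans and myeloid markers in 7 of 9, 1 adjusted over the list alone (camera adjusted p = 0.00423, adjusted p = 0.657 with an estimated correlation). The latter set shares H2-Aa, H2-Ab1, H2-Eb1 and Cd74 with the MHC list, so it is not a separate result. Cell cycle genes had a lower age effect in HFSC, with 3 of 30 higher and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0424, adjusted p = 0.978 with an estimated correlation). Camera called 9 lists in all and 0 with an estimated correlation (lowest adjusted p = 0.657), and fry called 0. With each of these 2, 3 of 45 lists had an unadjusted p under 0.05, near the number expected with no effect.

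EpdSC and HFSC of young mice were compared to describe what separates the populations at one age. Cd34 (ENSMUSG00000016494.9, chromosome 1, 194938821 to 194961292) was at 1761 ± 65.2 CPM in HFSC and 1.20 ± 0.863 CPM in EpdSC (log2 fold change -10.54, SE 0.413, edgeR adjusted p = 1.98e-08), and Ly6a (ENSMUSG00000075602.10, chromosome 15, 74994877 to 74998031) at 0.514 ± 0.163 and 175 ± 60.3 CPM (8.42, SE 0.36, edgeR adjusted p = 3.22e-08). Both proteins were used in the gates, so these values check the sort. Itga6 was higher in EpdSC (1.91, SE 0.17, edgeR adjusted p = 6.52e-06). The matrix protein gene Postn (ENSMUSG00000027750.16, chromosome 3, 54359267 to 54391041) was at 9389 ± 895 CPM in HFSC and 299 ± 6.21 CPM in EpdSC, and the BMP antagonist Grem1 at 890 ± 82.3 and 1.15 ± 0.0471 CPM (log2 fold change -9.59, SE 0.211, edgeR adjusted p = 8.1e-10). Il20ra, a subunit of interleukin receptors, was at 0.858 ± 0.178 CPM in HFSC and 231 ± 2.04 CPM in EpdSC (8.08, SE 0.209, edgeR adjusted p = 2.49e-09).

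In all 2788 genes were higher and 2812 lower in young EpdSC, with 1552 and 2205 at least 2-fold. The total of 5600 was 3668 without young EpdSC replicate 1. The other largest rises were H2-M2, a nonclassical class I gene that may share reads with other H2 genes (8.70, SE 0.605), the WNT agonist Rspo3 (8.69, SE 0.803), Ceacam12 (8.50, SE 0.845) and Bmp3 (7.89, SE 0.366). The other largest falls were the cytokine receptor Il31ra (log2 fold change -10.87, SE 0.547) and the adenylyl cyclase Adcy1 (-9.81, SE 0.53). Fitted folds against a group near 0 counts moved with 1 library. Without young HFSC replicate 1 Rspo3 had 13.23, Ceacam12 10.94 and H2-M2 7.69, and without young HFSC replicate 2 they had 7.83, 7.73 and 12.03. Adcy1 had -8.80 without young EpdSC replicate 1 and -13.36 without young EpdSC replicate 2. Cck, Kcnk10 and Nppc had no count in either young EpdSC library. Against a floor of 3 counts over that group (0.0456 CPM), Cck at 21.6 ± 3.36 CPM in HFSC was at least 474-fold higher there, Kcnk10 at least 335-fold and Nppc at least 149-fold. Of the 144 named genes called, 134 remained called whichever library was left out and all kept their sign, and 10 lost the call without young EpdSC replicate 1.

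Follicle lists were lower in young EpdSC. Of the 24 HFSC signature genes 20 fell over all genes and 20 adjusted over the list alone, among them the transcription factor Sox9 (-4.72), the WNT inhibitor Sfrp1 (-4.28) and Postn (-4.97) (camera adjusted p = 5.47e-13, adjusted p = 0.205 with an estimated correlation). Of 12 bulge markers 10 fell (10 adjusted over the list alone), among them Lgr5, a stem cell receptor of the follicle (-7.95) (camera adjusted p = 4.89e-08, adjusted p = 0.221 with an estimated correlation). Of 34 BMP and TGF-beta genes 22 fell and 5 rose (22 and 7 adjusted over the list alone), with Grem1 and Fstl1 (-7.75) lower and Bmp4 (6.56) higher (camera adjusted p = 0.000106, adjusted p = 0.205 with an estimated correlation). Of 40 matrix genes 18 fell, such as Ltbp2 (-8.86), and 5 rose, such as Tnxb (3.80), with 21 and 5 adjusted over the list alone (camera adjusted p = 0.000556, adjusted p = 0.311 with an estimated correlation). Of 20 genes of hair differentiation and hedgehog signalling 10 fell, such as the hedgehog effectors Gli1 (-6.09) and Gli2 (-6.07) and the hair keratin regulator Hoxc13 (-5.85), and 1 rose, the same numbers as adjusted over the list alone (camera adjusted p = 0.000544, adjusted p = 0.346 with an estimated correlation). Melanocyte markers fell in 5 of 8 (5 adjusted over the list alone), with Mitf, the regulator of pigment cells, at -4.21 (SE 0.249) and Dct at -4.67 (SE 0.389) (camera adjusted p = 0.00106, adjusted p = 0.221 with an estimated correlation). Of 8 fibroblast markers 4 fell (4 adjusted over the list alone), among them Fbln1 (-5.59, SE 0.307) and the collagen gene Col1a2 (-6.21, SE 0.566) (camera adjusted p = 0.0102, adjusted p = 0.433 with an estimated correlation). Of 12 sebaceous markers 5 fell and 2 rose (6 and 2 adjusted over the list alone) (camera adjusted p = 0.0355, adjusted p = 0.433 with an estimated correlation).

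Epidermal, immune and growth lists were higher in young EpdSC. Of 22 epidermal stem cell genes 17 rose, such as Ly6d (5.86), the desmoglein gene Dsg1a (4.34) and the transcription factor Gata3 (2.70), and 2 fell, with 18 and 3 adjusted over the list alone (camera adjusted p = 1.71e-07, adjusted p = 0.205 with an estimated correlation). Interfollicular basal markers rose in 9 of 11 (9 up and 1 down adjusted over the list alone), such as the ligands Wnt10a (2.82) and Wnt4 (2.45) (camera adjusted p = 4.77e-05, adjusted p = 0.205 with an estimated correlation). Of 18 MHC genes 15 rose (15 adjusted over the list alone), such as Nlrc5 (3.62) and H2-K1 (2.80), a class I gene close in sequence to other H2 genes (camera adjusted p = 4.89e-08, adjusted p = 0.346 with an estimated correlation). Langerhans and myeloid markers also differed, but H2-Aa, H2-Ab1, H2-Eb1 and Cd74 are in both this set and the MHC list, so the lists are not separate results. Of these 9 markers 6 rose, among them the class II genes H2-Aa (3.35) and H2-Ab1 (2.97) and the class II chaperone Cd74 (2.68), and 1 fell, Cd68 (-1.80), with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.243 with an estimated correlation). Of 25 cytokine genes 13 rose, such as Il33 (6.26) and Il1rn (5.88), and 2 fell, with Cxcl12 at -3.85, and 13 and 3 passed adjusted over the list alone (camera adjusted p = 0.000106, adjusted p = 0.277 with an estimated correlation). Of 20 JAK-STAT genes 13 rose, such as Il6ra (5.49) and Socs3 (2.43), and 2 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.000156, adjusted p = 0.311 with an estimated correlation). Of 23 immediate early genes 17 rose, such as Zfp36 (3.73), Junb (3.56) and Dusp1 (3.18), and 2 fell, with 18 and 2 adjusted over the list alone (camera adjusted p = 5.24e-07, adjusted p = 0.346 with an estimated correlation). Of 30 cell cycle genes 15 rose, such as Ccnd2 (1.98) and Cdc20 (1.77), and 1 fell, with 17 and 1 adjusted over the list alone (camera adjusted p = 0.000556, adjusted p = 0.346 with an estimated correlation). Of 42 ribosomal protein genes 25 rose, such as Rps9 (0.79), and 33 passed adjusted over the list alone (camera adjusted p = 1.54e-08, adjusted p = 0.433 with an estimated correlation). Camera called 26 lists, 17 of them upwards, and fry called 30.

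In aged mice the populations differed in 5180 genes, 2628 higher and 2552 lower in EpdSC, with 1485 and 2012 at least 2-fold. Cd34 was at 1141 ± 75.0 CPM in HFSC and 0.463 ± 0.174 CPM in EpdSC (log2 fold change -11.26, SE 0.438, edgeR adjusted p = 2.52e-08), and Ly6a at 1.74 ± 0.329 and 162 ± 33.6 CPM (6.54, SE 0.313, edgeR adjusted p = 7.54e-08). Itga6 was again higher in EpdSC (1.66, SE 0.169, edgeR adjusted p = 2.19e-05). Il31ra (log2 fold change -11.50, SE 0.594), the acetylcholine-synthesising enzyme gene Chat (-9.55, SE 0.301), Shisa2 (-9.42, SE 0.31), Grem1 (-9.39, SE 0.209) and Itm2a (-9.38, SE 0.494) were the other largest falls. The transcription factor Irf4 (6.79, SE 0.334), Bmp3 (6.73, SE 0.33), the protease Adamts14 (6.72, SE 0.225), the chemokine-scavenging receptor Ackr2 (6.63, SE 0.328) and Il20ra (6.43, SE 0.188) were the other largest rises. Without aged EpdSC replicate 2 Il31ra had -13.81 and Itm2a -8.46, without aged EpdSC replicate 1 -10.58 and -12.47, and without aged HFSC replicate 1 Irf4 had 7.74. Of the HFSC signature 20 of 24 genes fell, and 20 adjusted over the list alone (camera adjusted p = 9.82e-12, adjusted p = 0.268 with an estimated correlation). Of 30 cell cycle genes 20 rose, and 26 adjusted over the list alone (camera adjusted p = 2.15e-06, adjusted p = 0.272 with an estimated correlation), all 10 proliferating cell markers rose, 10 adjusted over the list alone (camera adjusted p = 0.000392, adjusted p = 0.444 with an estimated correlation), and 11 of 18 MHC genes rose, 12 adjusted over the list alone (camera adjusted p = 6.93e-05, adjusted p = 0.464 with an estimated correlation). Of 12 sebaceous markers 9 fell and 1 rose, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.000651, adjusted p = 0.272 with an estimated correlation). The young and aged comparisons shared 2178 rises and 2108 falls, against 341 and 334 for independent lists, with 1 gene called in opposite directions. They also shared the estimate of the spread for each gene, which may add to the overlap. The Pearson correlation of the fold changes of both comparisons across genes was 0.731.

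Promoter accessibility was compared between the populations and between the ages with 1 ATAC-seq library each, so the values describe these libraries without a replicate check. Over all promoters the log2 ratio of EpdSC to HFSC had a median of 0.10 in young and 0.94 in aged mice, and that of aged to young had a median of -0.73 in HFSC and 0.09 in EpdSC. Values of single genes are read against these medians. The Cd34 promoter had a log2 ratio of -4.39 ± 0.59 in young and -3.45 ± 0.757 in aged mice (± the 95% counting interval), Ly6a 5.37 ± 1.34 and 4.33 ± 1.80, Bmp3 3.21 ± 0.43 and 2.64 ± 0.642, and Il31ra -3.80 ± 0.426 and -1.27 ± 0.573. The 2546 genes higher in young EpdSC by RNA had a promoter median of 0.38 (random lists 0.064 to 0.107), and the 2452 lower genes -0.19 (random lists 0.078 to 0.123). In aged mice the 2330 higher genes had 1.22 (random lists 0.977 to 1.02) and the 2098 lower genes 0.57 (random lists 0.945 to 0.993). With age in HFSC, the 57 genes that rose in RNA had a promoter median of -0.14 (random lists -0.906 to -0.676). The 13 that fell had -0.97, inside the range of random lists (-1.04 to -0.588). The aged HFSC library had a flat signal, which can lower open promoters more than closed ones. Random lists were matched on RNA over all groups and not on accessibility in HFSC. Medians with that library may follow the flat signal, and those for HFSC are not read as a change with age. In EpdSC the 12 that rose had 0.41 (random lists -0.024 to 0.22) and the 6 that fell -0.99 (random lists -0.088 to 0.252). Ly6e was at 0.83 ± 0.536, Aff2 at 1.58 ± 0.713 and Peg3 at -1.14 ± 0.36 for aged against young HFSC. Casp12 was at 1.75 ± 0.396, Arc at 0.49 ± 0.159, Peg3 at -0.995 ± 0.442 and Ltbp1 at -0.98 ± 0.338 for aged against young EpdSC.

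**Figure D3:**
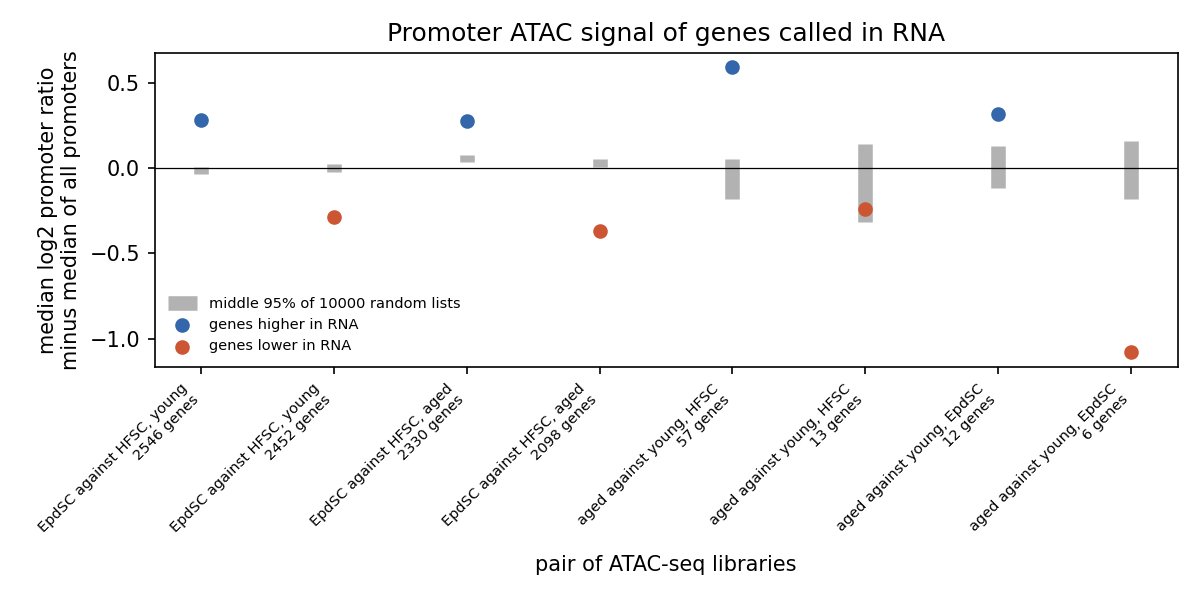
Median log2 promoter ratio of genes called in RNA, minus the median of all promoters, for each pair of ATAC-seq libraries; grey bars span the middle 95% of 10000 random lists. The 13 genes that fell in aged HFSC are the set whose median lies inside its bar. Pairs with the aged HFSC library may follow its flat signal, since random lists were not matched on accessibility.

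Between young EpdSC and HFSC 4659 of 49554 windows were at least 4-fold higher in EpdSC and 5964 lower. In aged mice the numbers were 7999 and 1430 of 41703, and with scaling to the median window 729 and 2492, against 4499 and 6072 in young mice. Log2 ratios of the young and the aged pair had a Pearson correlation of 0.919 across 37867 windows. Among the windows that differed in both pairs, one within the span of Tenm3 (chromosome 8, 49187001 to 49187500, mm10) had ratios of -4.70 in young and -4.44 in aged mice. Between the ages, 0 windows were higher and 356 lower in aged HFSC, of 33716, and with scaling to the median window 29 and 9. In EpdSC 4 were higher and 0 lower of 41913, and 3 and 0 with that scaling. The most covered 1% of windows held 17.8% of counts in the aged HFSC library and 32.3% to 34.4% in the other libraries.

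Single cells of both ages formed classes named from fixed markers, with 1 library per age and no test. Shares depend on the gate for integrin α6, on the cell filter and on the depth of each library. Interfollicular basal-like cells were 44.99% of aged (exact 95% interval 43.5 to 46.5) and 34.1% of young cells (32.7 to 35.6). At resolution 0.5 these cells were 5.04% of aged and 32.7% of young cells, and at resolution 1.5 30.6% and 32.3%. They lay in different clusters by age, and leading genes of these clusters differed between the libraries, so the shares describe each library and are not read as a difference between ages. Clusters 3 and 4, led by Gpnmb, Serpinb7 and Thy1, held 1200 and 328 aged and 52 and 7 young cells, and cluster 2 held 284 aged and 9 young cells. Cluster 0, led by H2-M2 and Cbr2, held 138 aged and 840 young cells, and cluster 1, led by the immediate early genes Atf3, Fosb and Fos, 60 aged and 469 young cells. A cluster mostly of 1 library may be that library and not a type. Bulge-like cells were 6.92% of aged (6.19 to 7.70) and 8.55% of young cells (7.71 to 9.46), suprabasal-like cells 13.9% and 11.8%, proliferating-like cells 6.24% and 6.42%, and sebaceous-like cells 1.97% and 1.07%. Upper hair follicle-like cells were 11.8% and 15.1%. Of these, cluster 7 held 181 aged and 410 young cells, and cluster 10 held 345 aged and 199 young cells. The bulge-like and upper hair follicle-like shares turned with the settings and are not read as a difference between ages either. Aged minus young was 2.57 percentage points for bulge-like cells at resolution 0.5 and 0.12 at resolution 1.5, and for upper hair follicle-like cells 0 at resolution 0.5, 3.9 at resolution 1.5 and 2.47 with 1000 UMIs or more. Suprabasal-like cells had 9.89 without the 3% highest doublet scores. The unnamed clusters 8 (led by Cldn10, Fam13a and Mfap2) and 9 (led by Sostdc1, Vsnl1 and Hpgd) held 6.27% and 7.99% of aged and 2.13% and 20.8% of young cells.

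Within classes, summed counts were set side by side. In aged bulge-like cells Ly6e was at 190 CPM against 42.6 CPM in young cells, a log2 ratio of 2.16 (1.61 to 2.74), and Thbs1, a matrix glycoprotein, at 323 against 72.0 CPM (2.17, 1.74 to 2.60). Igfbp3, an IGF-binding protein, was at 48.5 against 183 CPM (-1.92, -2.60 to -1.30), and the peptide hormone gene Cck at 24.2 against 170 CPM (-2.81, -3.80 to -1.97). Thbs1 is also in the interfollicular basal marker set. The suprabasal marker Krt1 was higher (2.018, 1.395 to 2.669) and the upper hair follicle marker Defb6 lower (-2.82, -3.43 to -2.27). Cluster 6, which made up this class, also counted markers of these last 2 sets, so these ratios may follow a different mix of cells by age. In interfollicular basal-like cells Amhr2 had a log2 ratio of 4.30 (3.28 to 5.54), Casp12 2.36 (1.63 to 3.16) and Krt6a, whose UMIs may be shared with Krt6b, 3.11 (2.59 to 3.67). The aged cells of this class lay mostly in cluster 3 and the young cells in clusters 0 and 1. Dbp, a clock output gene, was lower in aged cells in 4 classes, at 24.3 against 153 CPM in interfollicular basal-like cells (-2.66, -2.94 to -2.39). In suprabasal-like cells Casp1 had a ratio of 1.92 (1.33 to 2.55). In upper hair follicle-like cells Krt77 had a ratio of -2.50 (-2.78 to -2.23), but the aged cells of this class lay mostly in cluster 10 and the young cells in cluster 7, so the ratio may follow the mix of clusters. Of the immediate early genes, a list that was higher in bulk, 2 were among the lowest ratios here. Atf3 had a ratio of -4.01 (-4.65 to -3.43) in interfollicular basal-like cells, where it led cluster 1, which held mostly young cells, beside 0.61 in bulk EpdSC (edgeR adjusted p = 1). Fosb had -2.55 (-3.41 to -1.80) in upper hair follicle-like cells, with the same limit as Krt77. Barcodes called as cells held 87.8% of young and 82.9% of aged UMIs, and free RNA was not removed, so a ratio may hold RNA of other classes.

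Genes called with age in bulk were looked up in these classes, among those with at least 20 UMIs. Of the 79 HFSC calls 22 were measured in bulge-like cells, 13 of the 63 rises and 9 of the 16 falls. Of these 22, 18 moved the same way by their CPM, which is 81.8% (59.7 to 94.8). With a pseudocount of 0.5 there were 19, or 86.4% (65.1 to 97.1), since it turned Alox12e, at 18.2 CPM in aged and 18.6 CPM in young cells. With that pseudocount the 13 rises had a median log2 ratio of 0.84 (random lists -0.275 to 0.246) and the 9 falls -1.24 (random lists -0.445 to 0.417). Of the 18 EpdSC calls 10 were measured in interfollicular basal-like cells. All 10 moved the same way (69.2 to 100%), and the 8 rises had a median of 2.84 (random lists -0.424 to 0.306). Cadps2 had 29 UMIs in aged and 0 in young cells of this class, at least 11.5-fold higher against a floor of 3 counts over the class, and the median with it at this bound and without a pseudocount was 2.94. B2m was at 2675 CPM in aged and 1458 CPM in young bulge-like cells (0.88, 0.77 to 0.99), and Ltbp1 at 14.1 and 44.7 CPM (-1.66, -3.06 to -0.49). Ratios of both classes may follow a mix of cells or clusters that differs between the libraries.

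**Figure D4:**
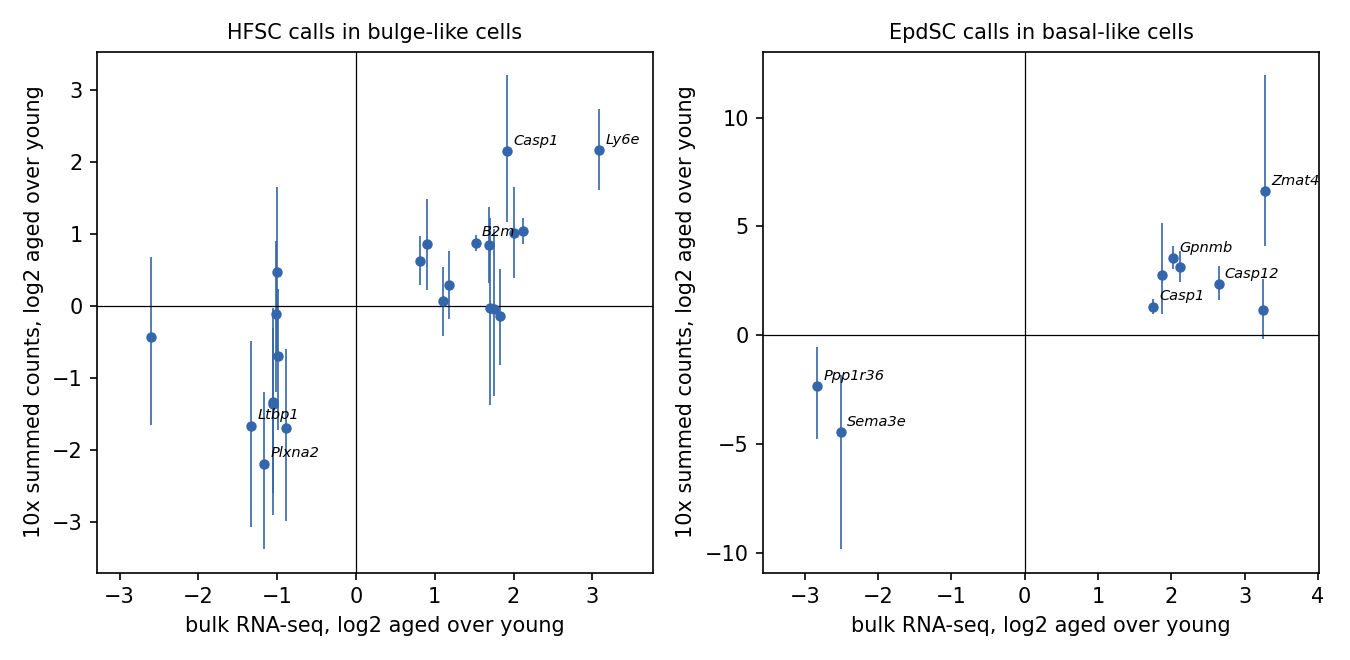
Log2 ratio of aged to young in summed 10x counts against the log2 fold change in bulk RNA-seq, for genes called in bulk; bars are 95% counting intervals. In the HFSC panel 18 of 22 points lie on the same side of 0 on both axes, and the EpdSC panel leaves out Cadps2, which had 0 UMIs in young cells.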

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

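Of the tests given here, the test of EpdSC cells in the aged HFSC sort and that of the depth of the single cells were written down before the result they measure was seen, and the others after it.

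Ly6e was singled out because its age effect differed between the populations in a direct test. The log2 age effect was 2.70 higher in HFSC than in EpdSC (SE 0.273, edgeR adjusted p = 0.0144, higher in both aged HFSC libraries). It lay between 2.39 and 2.94 when each library was left out, and the call was lost without aged EpdSC replicate 2 (2.65). Ly6e was at 9.08 CPM in young HFSC, 77.2 CPM in aged HFSC, 90.8 CPM in young EpdSC and 119 CPM in aged EpdSC.

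Of the 63 rises in aged HFSC, 36 were of genes that were also higher in EpdSC at both ages. EpdSC cells in the aged HFSC sort would bring all their abundant transcripts, but 116 such transcripts gained a median of 1.59% of their EpdSC level (1.25% and 1.65% in the 2 libraries), where these 36 rises needed 16.5% (10.9% and 18.7%). The 116 were chosen at a log2 fold change of at least 3 over HFSC in aged as in young mice, which limits the gain they can show. The 36 were chosen for a rise in the same aged libraries. Part of the gap is therefore built in, and it cannot tell EpdSC cells from another source. Within that limit the quartiles of the 116 were 0.451% and 2.95%, and 2 of the 36 needed no more than 2.95%. A few abundant transcripts taking a different share of the counts would move all other genes alike. Composition factors differed by at most 0.0679 in log2 between an aged and a young HFSC library, and the smallest of the 36 rises was 1.08. The fold changes were already scaled by these factors. Without them 63 rises and 12 falls were called in HFSC, and 67 of these 75 calls were among the 79 called with them. As far as the factors measure such a shift, these values argue against it. EpdSC cells in the sort stay open, and other keratinocytes that pass the gate and an age difference within HFSC stay open as untested.

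The aged HFSC library had a flat ATAC signal. After all 4 libraries were thinned to equal depth, its share of counts in the most covered 1% of windows still lay 14.9 percentage points below the lowest other library, which argues against depth. After scaling to the median window, 10.7% as many windows differed 4-fold between aged and young HFSC as before (38 against 356). The value shows a shift shared by most windows. More background in that library and a wide loss of accessibility would both give it, so it cannot tell them apart. With 1 library per group an age difference in chromatin stays open as untested.

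Interfollicular basal-like cells of both ages lay in separate clusters. The separation of the ages among neighbouring cells (0 for mixed libraries, 1 for separate ones) was 0.826 as sequenced and 0.607 with every cell thinned to 1000 UMIs, so an effect of the deeper young library cannot be told apart from another cause, since the value fell but stayed well above 0. An effect of the library on all cells alike cannot be told apart either, since the highest separation in another class was 0.75 as sequenced, close to these cells, and 0.493 after thinning, further below them. An age difference in these cells is confounded with the library and stays open as untested.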

How the results depend on the processing

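Alternatives chosen only after seeing the data were leaving out genes higher in young EpdSC, leaving out mitochondrially encoded genes and Rn7sk, summing both gene ends, thinning the ATAC libraries, leaving out the pseudocount in the direction of bulk calls in single cells, and removing the 3% of cells with the highest doublet scores; all others were planned. The choice between strand columns was not run, because there was 1 count column. Where a left-out library leaves a group with 1, that library is assumed to vary like the other groups. The cause of a change was not tested, except where fewer libraries or genes entered by construction. The lower depth of the aged HFSC ATAC library and of the aged cells limits the precision in them.

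DESeq2 called 367 genes with age in HFSC, 85 in EpdSC and 87 for the difference between the age effects, and 23 in the overlap of the age calls, and its calls included all 79 and all 18 of edgeR. Without a filter on low counts the numbers were 662, 239 and 285. With a filter of 1 CPM in 2 libraries there were 52 in HFSC and 10 in EpdSC, without the composition factor 11 in EpdSC, and in fits of only the 4 libraries compared 9 in HFSC and 3 in EpdSC. Without genes higher in young EpdSC 5 were called in HFSC, 4 rises and 1 fall. This adjusted the p-values of the other genes anew and left their folds and unadjusted p-values as they were. Of these other genes 18 rises and 14 falls were called before, so most passed only with the genes higher in young EpdSC in the adjustment. Leaving out each library in turn gave 12 to 161 in HFSC, 6 to 31 in EpdSC, 3668 to 5771 between young populations, 3606 to 5392 between aged populations, 0 to 63 for the difference and 3 to 8 in the overlap. Camera called 9 to 20 lists in HFSC, 2 to 10 in EpdSC and 23 to 27 between young populations in these fits. With an estimated correlation it called 0, 0 and 0, and fry called 3 in HFSC and 0 in EpdSC. Without mitochondrially encoded genes and Rn7sk 83 and 18 genes were called with age. All named called genes kept their sign in every fit with a library left out.

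With the replicate number as a block 160 genes were called in HFSC (123 rises and 37 falls) and 3 for the difference between the age effects, beside 23 in EpdSC. The block changed no other call count by over 1.5 times. Deviations of same-numbered libraries from their group means had correlations of 0.157 between aged and young HFSC, 0.174 between aged and young EpdSC, and -0.213 to -0.05 between the populations. The labels do not say what a number stands for, so the libraries were not treated as pairs, and a pairing within a population is not excluded.

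ATAC promoter medians kept their sign except with scaling to the median ratio, which gave -0.37 for genes lower in aged EpdSC than aged HFSC and 0.59 for genes that rose in aged HFSC. This scaling does not remove a flat signal that weighs more on open promoters. That scaling gave 0.28 and -0.29 for genes higher and lower in young EpdSC, 0.28 for genes higher in aged EpdSC than aged HFSC, and -0.24 for genes that fell in aged HFSC. Within 500 bases the medians were 0.30 and -0.23 in the young pair, 0.64 for lower genes in the aged pair and 0.57 for rises in EpdSC. Within 2 kb they were 0.43 in the young pair and 1.20 and 0.46 in the aged pair. With 50 counts or more they were 1.24 and 0.67 in the aged pair, -0.29 for rises in HFSC and 0.55 for rises in EpdSC. With both gene ends they were 1.14 and 0.40 in the aged pair and 0.61 for rises in EpdSC. Windows differing in the young pair, the aged pair, HFSC with age and EpdSC with age numbered 20500, 27233, 13987 and 186 at 2-fold, 3308, 1690, 6 and 0 at 8-fold, and 2980, 2470, 135 and 0 with 2 times the minimum count. Scaling to the median window gave 3221 in the aged pair and 38 in HFSC with age, and thinning gave 11 in EpdSC with age.

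Shares of single cells moved with the clustering. In percentage points of aged minus young cells, resolution 0.5 gave 2.57 for bulge-like, -27.69 for interfollicular basal-like and 0 for upper hair follicle-like cells, and resolution 1.5 gave 0.12, -1.64 and 3.9, so at resolution 1.5 all of them had the other sign. With 1000 UMIs or more the upper hair follicle-like value was 2.47, with doublets kept -4.99. With 20% mitochondrial UMIs interfollicular basal-like cells had 5.96 and upper hair follicle-like cells -9.67. Without the 3% highest doublet scores the values were 4.39 for interfollicular basal-like, 9.89 for suprabasal-like and -5.89 for upper hair follicle-like cells. Of the genes named within classes, 43 were the same with thinned cells and 16 moved by more than their interval, and 51 and 9 with 1000 UMIs or more. The share of HFSC calls with the same direction in bulge-like cells was 73.2% with DESeq2 calls, 81.8% with doublets kept and 81.8% without a pseudocount.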

Other observations

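No test is added in this part, and the genes called with age in it were chosen after their values were seen.

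Other genes called with age in EpdSC and not described above were Gpnmb, a membrane glycoprotein, which rose from 29.0 to 118 CPM (log2 fold change 2.02, edgeR adjusted p = 0.007), Fam180a (2.12, edgeR adjusted p = 0.0387), Slit3, a secreted guidance cue (1.87, edgeR adjusted p = 0.0253), and Ppp1r36 (-2.83, edgeR adjusted p = 0.0447). In single cells Gpnmb led the clusters that held most aged interfollicular basal-like cells. Among genes that differed between young populations, the neurotrophic factor receptor gene Gfra1 (log2 fold change -9.02) and the adhesion gene Nrcam (-8.16) were lower in EpdSC, and the guidance genes Robo1 (4.14) and Sema3d (4.85) were higher.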
